A study of Rattus norvegicus with 6 samples.

How the data were processed

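Stranded mRNA-seq libraries had been made from the spinal cord of 6 rats, 3 per group, and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC 0.11.2, STAR 2.5.3a, StringTie 1.3.1c and the rat genome build rn6, without saying which step each served. The program that counted reads per gene, its strand setting and the annotation release are not given in the sources used here.

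The authors deposited one table of 22526 Ensembl rat gene IDs by 6 libraries, with values on a log2 scale from 0 to 19.8. The unit was worked out from the values. After the log2 was undone and 1 was subtracted, 100% of the values in each library were whole multiples of one step, within a tolerance of 0.05 reads, and the largest deviation was 0.0017 reads. The inverse steps, 0.927 to 1.05, were the median-of-ratios size factors of the resulting whole numbers. The deposited values are therefore log2(read count / size factor + 1), with 1 added to each normalized count before the log. Every listed gene had a read in at least 1 library. The values are called normalized counts here on the linear scale, and the whole numbers are called recovered reads.

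Recovered totals ran from 24961512 to 31189687 reads per library, so that the 3 reads that a count of 0 allows are a share of 9.62e-06% to 1.20e-05% of a library. Such limits cover counting error only, because the labels' protocols mention no molecular identifiers. Replicates are separate rats in the series' design. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over genes lay between 23.1 and 752.7 for the 15 pairs of libraries.

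The table gives Ensembl IDs and no gene names, and none of its 22526 IDs was found in the reference gene table at hand, which lists 47357 genes under other identifiers. The 42 gene lists fixed before the data were examined (markers of neurons, glia, immune cells, vessels, other tissues, and pathways) could therefore not be matched, and no list was tested. The fixed rule for naming genes took the largest folds in each direction among genes past the threshold whose groups do not overlap and whose mean level is at or above the median of the tested genes. It also asked for a gene symbol and for a fixed panel of symbols, which could not be applied, and it was limited here to 2 IDs per direction. Gene positions, lengths and base composition are not used here.

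A-DON was compared with DON by limma 3.58.1 (R 4.3.3, statmod 1.5.0), with a linear model on group alone, an intensity trend and robust moderation, on the deposited log2 values of genes with a normalized count of at least 1 in at least 3 libraries. The design fixed before the data were examined called for this test where the table held normalized values, so it was kept as the main test, and the recovered reads were tested only in an added alternative (voom). P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. All fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. The test was checked on simulated counts for the real genes (negative binomial, dispersion 0.05, real size factors, 19316 genes kept). It recovered 40% of 100 genes changed 2-fold and 86% of 100 genes changed 4-fold, and called 6 unchanged genes. Every simulated gene had the same dispersion, 200 genes were changed, and libraries of a group shared the same means. These figures therefore do not measure recovery or false calls in the real data.

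Alternatives fixed in advance were rescaling, quantile normalization, no filter, a mean of at least 5, limma without trend and robust moderation, a pseudocount of 0.1, the replicate number as a block, and leaving out each library. Total-count scaling, a filter of 10 reads in 3 libraries, limma's voom on the recovered reads, per-library sample weights and thinning to equal depth were added after seeing the data. The titles give rats 1 to 3 in each group. Rats with the same number did not deviate together from their group means, so the numbers were not used to pair rats.

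The place of each library between the groups was computed gene by gene as (value minus the mean of the other group) divided by (mean of the other 2 libraries of its own group minus the mean of the other group). A position of 0 is thus the other group and 1 the rest of the library's own group. It used genes with a mean of at least 50 normalized counts and a difference of at least 4-fold whose remaining libraries did not overlap, chosen without the library being placed. Minimums of 2-fold and 8-fold, and means of 10 and 200 normalized counts, were alternatives added after seeing the data. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.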

Results

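Spinal cord RNA was profiled in 6 adult Sprague-Dawley rats 2 weeks after spinal cord injury. The series describes all of them as female, which was not checked here. In 3 rats the lesion had received a decellularized optic nerve scaffold, that is, optic nerve stripped of its cells (DON). In the other 3 it had received the same kind of scaffold carrying Apt19S, an aptamer, which is a short single-stranded nucleic acid that folds to bind a target (A-DON). There was no uninjured or unimplanted group, so DON is the only reference. DON replicates 1 to 3 held 31189687, 30432009 and 29143139 recovered reads, and A-DON replicates 1 to 3 held 28911941, 24961512 and 28270110. The mean was 30254945 ± 1034700 reads (SD, n = 3) in DON and 27381188 ± 2119931 (SD, n = 3) in A-DON. Between 16403 and 16782 genes had at least 10 reads in a library.

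The comparison asked what the aptamer added to the scaffold changed in the transcriptome of the implanted cord. A-DON and DON cords differed in 6930 of 19515 tested genes (35.5%; limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 3698 were higher in A-DON and 3232 were lower. The change was at least 2-fold in 2612 of the higher and 1927 of the lower genes, and at least 8-fold in 501 and 148. Over all tested genes the log2 fold change ran from -2.38 at the 5th percentile to 2.45 at the 95th, with a median of -0.02. The difference reached abundant and scarce transcripts: 4293 of the 9758 genes in the upper part of the level range (44.0%) and 2637 of the 9757 in the lower part (27.0%) passed the test. The 3 A-DON values lay entirely above the 3 DON values in 5466 genes and entirely below in 5437. Together these are 55.9% of the tested genes. Without ties, the average over all 10 splits of the libraries into 3 and 3 is 10%. Genes vary together across libraries, so the excess over 10% does not measure how unlikely the grouping is.

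**Figure D1:**
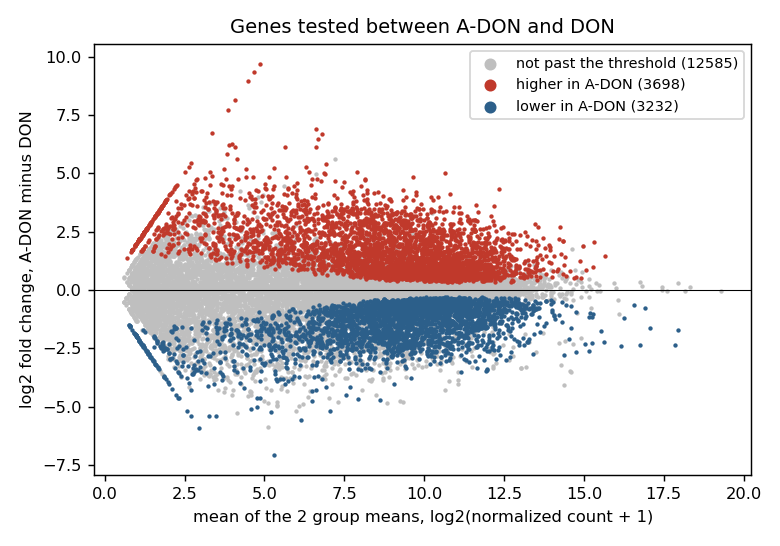
Log2 fold change (A-DON minus DON, vertical axis) of each of the 19515 tested genes against its mean level (horizontal axis, log2(normalized count + 1)). Red points are the 3698 genes higher in A-DON, blue points the 3232 lower, and grey points did not pass the adjusted p threshold of 0.05.

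The 2 genes chosen by rule among those higher in A-DON were ENSRNOG00000047712 and ENSRNOG00000059479. ENSRNOG00000047712 rose from 290.1 ± 107 normalized counts (SD, n = 3) in DON to 9245 ± 1811 (SD, n = 3) in A-DON. Its log2 fold change was 5.03 with a standard error of 0.28 and a limma adjusted p of 0.0046. ENSRNOG00000059479 rose from 171 ± 112 to 4322 ± 1078 normalized counts (SD, n = 3 each), a log2 fold change of 4.83 with a standard error of 0.47 and a limma adjusted p of 0.0078. The 2 chosen among genes lower in A-DON were ENSRNOG00000061379 and ENSRNOG00000019890. ENSRNOG00000061379 fell from 2730 ± 2715 to 134 ± 168 normalized counts (SD, n = 3 each), a log2 fold change of -4.71 with a standard error of 1.09 and a limma adjusted p of 0.025. ENSRNOG00000019890 fell from 2306 ± 1133 to 334 ± 493 normalized counts (SD, n = 3 each), a log2 fold change of -4.02 with a standard error of 1.18 and a limma adjusted p of 0.043. Within A-DON the 2 lower genes had log2 SDs of 1.88 and 2.41 and the 2 higher genes of 0.28 and 0.35, while within DON the SDs of the lower and higher genes overlapped. On the linear scale the order in A-DON was reversed, with SDs of 168 and 493 normalized counts for the lower genes and 1811 and 1078 for the higher. The larger spread of the lower genes thus holds for the log2 scale only. In A-DON replicates 1, 2 and 3, ENSRNOG00000019890 had 44.3, 903.0 and 55.4 normalized counts. Leaving out any single library kept ENSRNOG00000047712 past the threshold, while ENSRNOG00000059479 lost its call without A-DON replicate 1 or 3 (limma adjusted p of 0.050 and 0.059; log2 fold changes of 4.63 and 4.97). ENSRNOG00000061379 and ENSRNOG00000019890 lost theirs without any library other than A-DON replicate 2, with limma adjusted p of 0.051 to 0.095 and of 0.079 to 0.14. Their log2 fold changes in these fits were -5.16 to -3.93 and -4.28 to -3.25, and each of these fits had fewer rats. Without A-DON replicate 2 the log2 fold changes of these 2 genes were -5.766 and -5.405, with limma adjusted p of 0.00443 and 0.000998. The files used here pair no gene name or position with these IDs.

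Rats differed within both groups, with a median SD over genes of 0.29 in A-DON and 0.28 in DON on the log2 scale, but along different components. The first principal component held 70.5% of the variance and separated the groups, with scores from -113 to -71.0 in DON and of 144 and 128 in A-DON replicates 1 and 3. A-DON replicate 2 scored 15.6. On the second component (9.8% of the variance) DON replicate 1 stood apart, at 73.3 against -50.7 and -33.0 in DON replicates 2 and 3. Across genes, Pearson's r between libraries was 0.960 to 0.971 within DON and 0.983 between A-DON replicates 1 and 3. A-DON replicate 2 had an r of 0.941 and 0.947 with the other A-DON libraries and of 0.933 to 0.950 with the DON libraries. Genes are not independent replicates, so these coefficients describe the libraries only.

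**Figure D2:**
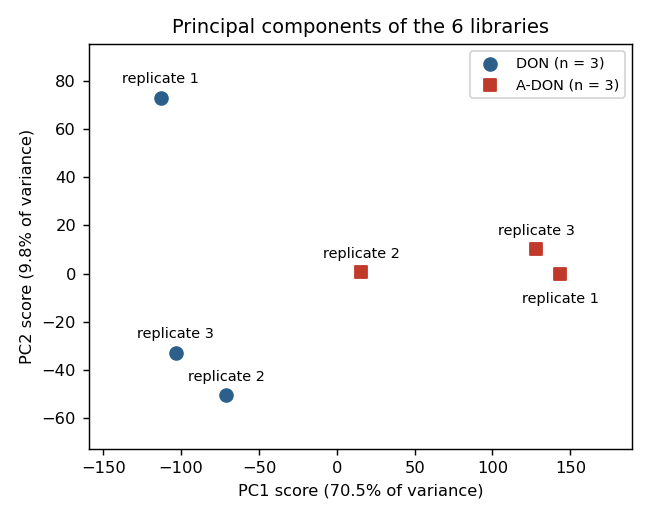
Scores of the 6 libraries on the first (horizontal, 70.5% of the variance) and second principal component (vertical, 9.8%) of the log2 values, without units. Blue circles are DON and red squares A-DON, and A-DON replicate 2 at 15.6 lies between the DON libraries and the other A-DON libraries on the first component.

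The number of genes past the threshold depended on single libraries. Without A-DON replicate 2 there were 9286 genes past the threshold, 4431 higher and 4855 lower. Without A-DON replicate 1 or 3, 35 and 12 genes passed it, of which 34 and 12 were among the 6930, although 6838 and 6851 genes had an unadjusted limma p under 0.05. In these fits A-DON was left with the intermediate replicate 2 and a single other library, and there were fewer residual degrees of freedom. The low counts therefore do not show that the difference is carried by replicate 1 or 3. Without DON replicates 1, 2 and 3 the counts were 3890, 3930 and 1552. Of the called genes 53.4% were higher in A-DON with all libraries, and 66.7%, 71.9% and 85.8% without DON replicates 1, 2 and 3, as the lower genes fell to 1297, 1105 and 220. The share was 91.4% and 91.7% without A-DON replicates 1 and 3, and 47.7% without A-DON replicate 2. Scaling to equal library totals gave 64.4%.

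The intermediate place of A-DON replicate 2 was measured on 1062 genes at least 4-fold higher and 1650 genes at least 4-fold lower in the other A-DON libraries than in DON. On the linear scale of normalized counts its median position between DON (0) and the other A-DON libraries (1) was 0.56 for the higher genes (quartiles 0.49 and 0.64). It was 0.52 for the lower genes (quartiles 0.39 and 0.64). On the log2 scale the medians were 0.78 and 0.27. Placed in the same way on the linear scale, DON replicates 1, 2 and 3 had median positions of 0.61, 0.62 and 0.65 for genes higher in DON and of 1.05, 0.87 and 1.04 for genes lower in DON. A-DON replicate 1 had 1.40 for genes higher and 1.14 for genes lower in A-DON, and A-DON replicate 3 had 1.13 for both. The positions thus differed between the kinds of genes by more in all DON libraries and in A-DON replicate 1 than in A-DON replicate 2. Genes were chosen on the other 2 libraries of the own group. That choice alone can move any library left out below 1, A-DON replicate 2 included. The own-group mean of A-DON replicates 1 and 3 held replicate 2, which can move them above 1. How much of each position comes from these choices was not tested.

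**Figure D3:**
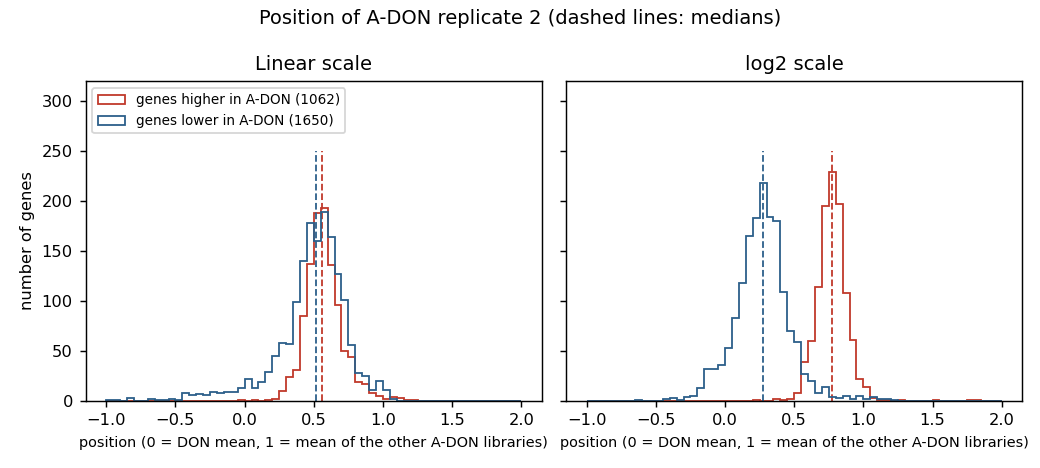
Number of genes (vertical axis) by the position of A-DON replicate 2 between the DON mean (0) and the mean of the other A-DON libraries (1), on the linear scale (left) and the log2 scale (right). Red lines are the 1062 genes higher and blue lines the 1650 genes lower in A-DON, with dashed medians of 0.56 and 0.52 on the linear scale and 0.78 and 0.27 on the log2 scale. On the linear scale 12 genes outside -1 to 2 are not drawn.

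A small group of genes was read in one group only. In 17 genes all 3 DON libraries had 0 reads and every A-DON library at least 10, and in 5 genes the reverse held. The most abundant of the 17 were 5 genes with 113 to 1457 reads in each A-DON library. The 5 genes read in DON only had at most 69 reads in a library. A count of 0 allows up to 3 reads per library. The chromosomes of these genes were not used here, so whether any is linked to sex, and whether it bears on the labelled sex of the rats, was not checked. In 4 of the 5 abundant genes the level was 2.52 to 3.14 times higher in A-DON replicate 1 than in replicate 3, and 1.89 to 2.18 times higher in replicate 2 than in replicate 3. The fifth had a ratio of 1.03 between replicates 1 and 3 and of 0.50 between replicates 2 and 3. Of all 12484 genes with at least 100 reads in every A-DON library, 57 (0.457%) were 2-fold or more higher in replicate 1 than in replicate 3, and the median ratio was 1.00.

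**Figure D4:**
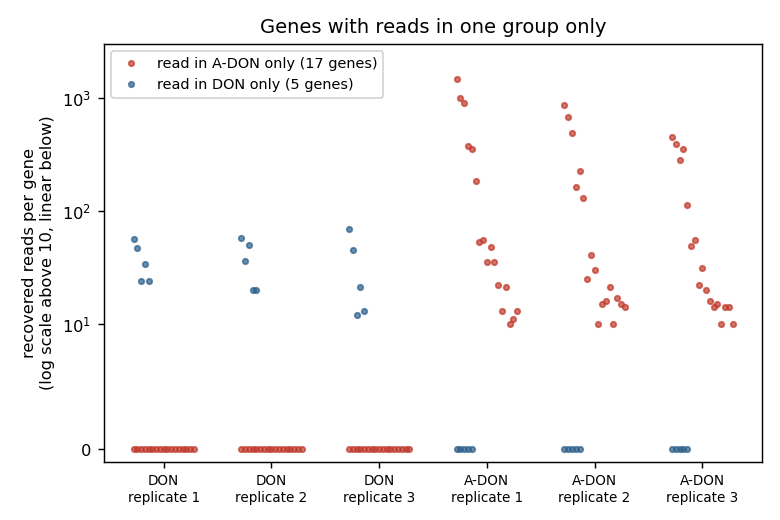
Recovered reads per gene (vertical axis, log scale above 10 and linear below) in the 6 libraries (horizontal axis), with each point 1 gene and genes set side by side within a library. Red marks the 17 genes with no read in DON and blue the 5 genes with no read in A-DON. The 5 uppermost red genes hold 113 to 1457 reads in each A-DON library.

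The most abundant genes held a smaller share of the reads in the A-DON libraries. The 10 most abundant genes of a library held 12.1 ± 1.27% of its reads (SD, n = 3) in DON and 9.33 ± 1.14% (SD, n = 3) in A-DON. Every A-DON library lay below every DON library, with an exact two-sided permutation p of 0.1, the smallest that 3 rats against 3 allow. Totals were also lower in every A-DON library than in every DON library (exact two-sided permutation p = 0.1). After all libraries were thinned to the smallest total, 6821 genes passed the threshold.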

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

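The settings named as chosen after seeing the data in the account of the processing are total-count scaling, the filter on reads, voom, sample weights and thinning. The count of genes past the threshold (6930) kept within 1.5 times under 10 of the settings other than leaving out a library, from 5879 genes (limma without trend and robust moderation) to 7356 (voom on the recovered reads), and 5654 to 6929 of the genes called there were among the 6930. Median-of-ratios rescaling, which the deposited values already carry, left the count at 6930 and shared 6929 calls, so it tests nothing. With the replicate number as a block, 0 genes passed in either direction (limma), while 7601 had an unadjusted p under 0.05. That fit leaves 2 residual degrees of freedom, and rats sharing a number did not deviate together (r = -0.17, -0.24 and -0.08), with no A-DON rat correlating best with its own number. Sample weights gave A-DON replicate 2 a weight of 0.24 and DON replicate 1 a weight of 0.41, against 6.99 for A-DON replicate 3. They raised the count to 12414, with 6153 higher and 6261 lower, and the cause was not tested. Leaving out 1 library gave 12 to 9286 genes in all, 11 to 4431 higher and 1 to 4855 lower. The lowest counts came without A-DON replicate 3 and the highest without A-DON replicate 2; fits without a library have fewer residual degrees of freedom. The 4 named genes kept their direction under all 18 settings and lost their call in 1 (ENSRNOG00000047712), 3 (ENSRNOG00000059479), 6 (ENSRNOG00000061379) and 7 (ENSRNOG00000019890) of them, with adjusted p up to 0.066, 0.066, 0.095 and 0.14. With a minimum of 5 or 20 reads, 47 or 9 genes were read in A-DON only and 16 or 3 in DON only, and the 5-read and 20-read minimums were chosen after seeing the data. The fixed gene lists gave no value under any setting, for want of gene names. Recovery was lower with low genes included: in simulated data 57.1% of 2-fold changes were recovered at a mean of 50 or more normalized counts, against 40% over all levels. Depth was not varied in the simulation, so its part in this was not tested.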

Other observations

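The count of 6930 genes and the leaving out of single libraries were planned. The tests of explanations in this part (splits, thinning, positions, genes without reads and ratios between replicates) and the sample weights were chosen after the patterns had been seen in the same data, so each explanation is a hypothesis.

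The count of 6930 genes between A-DON and DON came from the real split of the 6 libraries, which is 1 of 10 splits into 3 and 3, and the highest count of another split was 0 (limma; up to 1364 genes at an unadjusted p under 0.05). With 10 splits no share under 0.05 can be had. Every other split puts libraries of both groups on each side, so a large difference between the groups widens its spread and lowers its count. The 0 is therefore no measure of what chance gives. A difference in depth is argued against as the cause, because 6821 genes passed after thinning to equal totals. What stays open, and untested, is how much of the difference comes from the aptamer and how much from what was sampled. A genetic difference between the rats of the groups, or a further RNA source in the A-DON libraries, stays open too. These causes are taken up below for the genes read only in A-DON or only in DON. Their part in the wider difference was not tested. Each rat gave one library, so the piece of cord taken cannot be told apart from the rat. Tissue content was not measured, because no gene could be named.

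A-DON replicate 2 lies between the groups, and the libraries may hold the same RNA sources in different shares, such as more or less scaffold, scar or spared cord in the dissected piece, in which case rising and falling genes should give one position on the linear scale. Their median positions in this library differed by 0.044 on the linear scale and by 0.502 on the log2 scale. In 4 of the other 5 libraries the linear gap was over 0.2 in size (-0.45, -0.24 and -0.39 in DON replicates 1 to 3 and 0.26 in A-DON replicate 1). Those gaps rest on other sets of genes (217 falling genes for A-DON replicate 1 against 1650 for replicate 2). For A-DON replicates 1 and 3 the own-group mean also holds the intermediate replicate 2. The other gaps are therefore no like-for-like yardstick, so the small gap decides nothing and shares stay open. At a 2-fold minimum the linear medians of A-DON replicate 2 for rising and falling genes were 0.534 and 0.563, and at an 8-fold minimum 0.578 and 0.481. Of 23 genes with no read in A-DON replicates 1 and 3 and at least 20 in every DON library, 20 had reads in A-DON replicate 2, and the 23 together had 1107 reads where RNA or reads of DON libraries mixed into A-DON replicate 2 would give 584. The other 3 had 0 reads where such mixing predicts 52.9, at the share of 45.7% from DON that the median position gives. These 3 are among the genes read in DON only, so their 0 reads were already known. Their absence goes against mixing with these DON libraries as the whole cause, and equally against shares of sources alike in all rats. It does not go against shares of tissue in rats that differ in these 3 genes, which was not tested. Dissection and a lesser tissue response in this rat stay open as well. Among the settings run, lower genes outnumbered higher ones when this library was left out (4855 against 4431) or given little weight (6261 against 6153). The sample weights also gave DON replicate 1 only 0.41 and A-DON replicate 3 6.99, so that count does not single out this library.

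The genes read in one group only numbered 22 in the real split and at most 3 in any other split. None of the 22 can be read on a single side of another split, so these counts do not measure chance. Of the 5 abundant ones, 4 differed 2-fold or more between A-DON replicates 1 and 3, which are otherwise nearly alike, and placed replicate 2 at 0.92 to 1.08, which argues against the shares of RNA sources that place A-DON replicate 2 between the groups as the cause for these 4; the fifth, with ratios of 1.03 (replicates 1 to 3) and 0.50 (replicates 2 to 3), goes with such shares. A genetic difference carried alike by every cell of the A-DON rats stays open. The median replicate 1 to 3 ratio over the 5 was 3.033, reached by 0.096% of all genes at that depth, so levels were not alike in these rats. The 5 were chosen by their reads and not by this ratio. Such a difference need not give equal levels in each rat, however, so the ratio cannot decide. Of the 17 genes read in A-DON only, 9 had a ratio of 2 or more, and some others were near 1 (1.10 for ENSRNOG00000037621 and 0.94 for ENSRNOG00000006122). One further RNA source present in different amounts in the A-DON libraries, such as cells of another genotype or sex, stays open: the replicate 2 to 3 ratios of the 4 spanned 1.156 times from lowest to highest, but 1.53 times with the next most abundant such gene (2.89), and they ran from 0.55 to 2.89 over all 9 genes with a replicate 1 to 3 ratio of 2 or more, some with few reads. The genes were picked by a ratio with the same denominator, and with gene names and chromosomes not used here, neither sex linkage nor a biological explanation from the design was tested.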
